A study of Mus musculus with 12 samples.

How the data were processed

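RNA was measured in B cells of the germinal centre (GC), the structure of a lymphoid organ where B cells divide, mutate their receptors and are selected. Donor B cells carrying a receptor for hen egg lysozyme (SwHEL) had been transferred into mice that were immunized with sheep red blood cells coupled to the lysozyme mutant HEL3x. Per the labels, donor GC cells (IgG1+, CD38 low) were sorted from spleen on day 10 into light zone (LZ: CD86 high, CXCR4 low) and dark zone (DZ: CXCR4 high, CD86 low) cells of high or low affinity. Amplified, biotin-labelled cDNA was hybridized to 12 one-colour arrays, 3 in each of 4 groups (DZ_high, DZ_low, LZ_high and LZ_low). The labels do not state how affinity was gated or whether the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

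The deposited values are log2 RMA expression values per probe set, with 1 column per sample. RMA and the genome build mm8 are all that the submitters' processing notes name, and the log base was taken from the range of the values, 1.99 to 13.74. The sorted probe set values differed between arrays, which does not show whether normalization was done before the values were summarized to probe sets. No scanner files or detection p-values were available, and no coordinates were used. Of 28853 probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 had none. Of the 21789, 21698 matched the reference gene table by gene ID, and 0 symbols differed. A gene was taken as a probe set with 1 symbol; where a gene had more than 1 (999 of 19938 genes), the one with the highest mean over all arrays was used. A gene was tested when at least 3 of the 12 arrays had a value at or above that array's median over all probe sets. This left 11206 genes, of which 10668 are protein coding, and 8732 genes were too dim. Cd38 and Ighg1 had no probe set of their own and Prdm1 was too dim, so none of these was tested.

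Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The 7 contrasts were LZ minus DZ (the mean of both affinities, and at high and at low affinity), high minus low affinity (in LZ, in DZ and the mean of both zones), and the interaction of zone and affinity, which is the affinity difference in LZ minus that in DZ. Values are log2 differences with the standard error (SE) of the fit. Before the data were examined, 24 gene lists were fixed from textbook knowledge, none of them chosen on these samples; 23 had at least 5 tested members, and the erythroid list, with 3, was not tested. Each was tested in 5 of the contrasts with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. A list's value is the median log2 difference of its members; members past the threshold were also counted when adjusted over the list alone. The lists share members: light zone markers hold 8 of the NF-kB targets and 5 of the immediate early genes.

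The contrasts, lists, filter and the rule for named genes were fixed before the data were examined. That rule named the 8 largest rises and 8 largest falls among called genes that changed the same way in every matched set, filled from the fit with the replicate block where a direction had fewer. Where none was called, it named the 3 genes with the smallest p in each direction. It also took up to 4 members with the smallest p of each list named in the text, and always the sort genes and a fixed set of B cell regulators. Predicted genes and receptor segments were counted and not named.

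Each group has 1 array with each of 3 suffixes in the sample descriptions, which was read as a shared batch or day and defines matched sets 1 to 3. The replicate numbers below are those of the matched sets. With group means removed, 17 of the 18 pairs of arrays from the same set had a correlation across genes above 0.1 (median 0.41, lowest -0.071), and 11 of 12 arrays correlated best with an array of their own set. The fit with matched set as a fixed block was named as an alternative before the data were examined. The check of the pairing was made after the counts of both fits were known, so the fit without the block was kept as the one reported first. Blocked values are given beside it for the counts and for part of the genes and lists.

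Other alternatives were a random block, no filter or a stricter one (percentile 75 in place of 50), a new quantile normalization, centring on the array median, eBayes with trend and robust, array weights, all probe sets, a fold minimum of 1.5, only the groups compared, the mean of a gene's probe sets, and leaving out each array. Fits without matched set 3, blocked fits without that set or without its LZ_high array, and the block with an estimated correlation or with fry were added after seeing the data. The arrays' number limits the precision. The fits were tested on 10 simulated data sets of 11206 genes, 200 of them changed. For LZ minus DZ, 30.0% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 89.8% of those changed 3-fold were called without the block. For the affinity contrast in LZ the shares were 6.8%, 41.6% and 77.0%. With the block they were 45.4%, 84.6% and 95.0% for LZ minus DZ and 18.6%, 60.2% and 87.4% for affinity in LZ. False calls were 1.0% and 1.9% of the calls without the block, and 6.1% and 5.1% with it. A list shifted by 0.4 was called in 10 of 10 simulations of either contrast. With no change, 1 list in all was called for affinity in LZ and 0 for LZ minus DZ. The simulated genes varied independently of each other, so these counts do not measure false calls of lists whose members move together. Other splits of the real arrays called up to 13 lists for LZ minus DZ and up to 5 for affinity in LZ. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.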

Results

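Gene expression was measured in sorted mouse GC B cells of the light and dark zone, each at high and low affinity for the lysozyme antigen, with 3 arrays in each of the 4 groups. Array medians lay between 5.57 and 5.71 on the log2 scale, and the correlation between 2 arrays lay between 0.872 and 0.986. The first principal component held 40.1% of the variance and the second 16.8%. The 4 arrays of matched set 3 stood apart on the first component, with scores from 12.5 to 52.9 against -26.4 to -6.7 for the other arrays. The LZ_high array of that set had the lowest mean correlation with the others, 0.897.

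**Figure D1:**
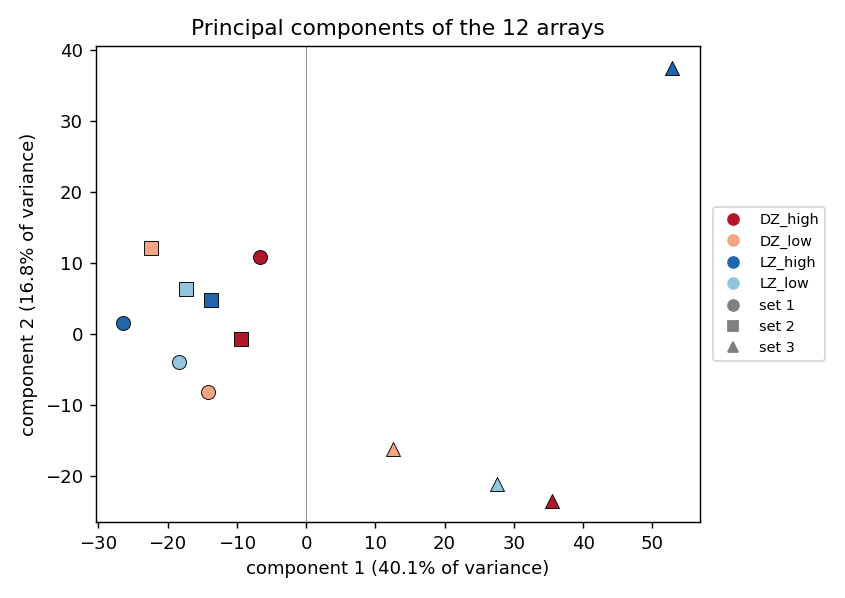
Scores of the 12 arrays on the first and second principal components over the tested genes (arbitrary units, with the percent of variance on each axis); colour gives the group and shape the matched set. The 4 arrays of set 3 have scores from 12.5 to 52.9 on the first component and the other arrays from -26.4 to -6.7.

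The first comparison asks how LZ cells, which take up antigen and meet T cells, differ from DZ cells, which divide and mutate. LZ cells had higher expression of the transcription factor gene Hhex, 2.04 ± 0.21 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0018; probe set 10462818), and of Fcer2a, which encodes the low-affinity IgE receptor CD23, 1.70 ± 0.13 (adjusted p = 0.000353; probe set 10576757). The 4-1BB ligand gene Tnfsf9 was higher by 1.69 ± 0.21, the activation marker Cd83 by 1.60 ± 0.14 and Egr2, a transcription factor induced by antigen receptor signalling, by 1.51 ± 0.18. Selenop, which encodes a selenium transport protein, fell by 1.84 in LZ cells (SE 0.21, adjusted p = 0.00362; probe set 10422598), Ptgr1, a prostaglandin reductase, by 1.81 (SE 0.25) and the membrane protein gene Serinc5 by 1.29 (SE 0.17). The other genes with the largest rises were Serpinb1a (1.45), the aldolase gene Aldoc (1.42) and the B cell co-receptor gene Cd72 (1.30). The other genes with the largest falls were Adhfe1 (-1.39), Pafah1b3 (-1.38), the deubiquitinase gene Otub2 (-1.23), the poly(A) polymerase gene Tent5c (-1.15) and the sodium channel gene Scn11a (-1.14). Of the genes used for sorting, Cd86 was higher in LZ cells by 1.13 ± 0.11, as its gate requires, and Cxcr4 had a difference of -0.63 ± 0.18 (adjusted p = 0.271, 0.0449 with the replicate block and 0.0282 with array weights). All of the genes named so far moved the same way in 6 of 6 pairs of arrays. The naming rule required this of all but the sort genes Cd86 and Cxcr4, so it is no separate support for the others. In all, limma called 47 of 11206 genes, 26 higher and 21 lower in LZ cells, and 135 with the replicate block (79 higher, 56 lower), which held all 47; 46 of the 47 moved the same way in every pair. Leaving out any 1 array other than DZ_high replicate 3 or LZ_high replicate 3 lowered the count by more than 1.5 times, to between 12 (without DZ_low replicate 1) and 28 (without DZ_low replicate 3 or LZ_low replicate 3). Hhex, Fcer2a, Tnfsf9, Cd83, Egr2, Cd86, Selenop, Ptgr1 and Serinc5 passed in each of the 12 fits without 1 array, while Adhfe1 was lost in 11, Scn11a, Serpinb1a and Tent5c in 8 each, Cd72 in 7, Otub2 in 6, and Aldoc and Pafah1b3 in 5 each.

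**Figure D2:**
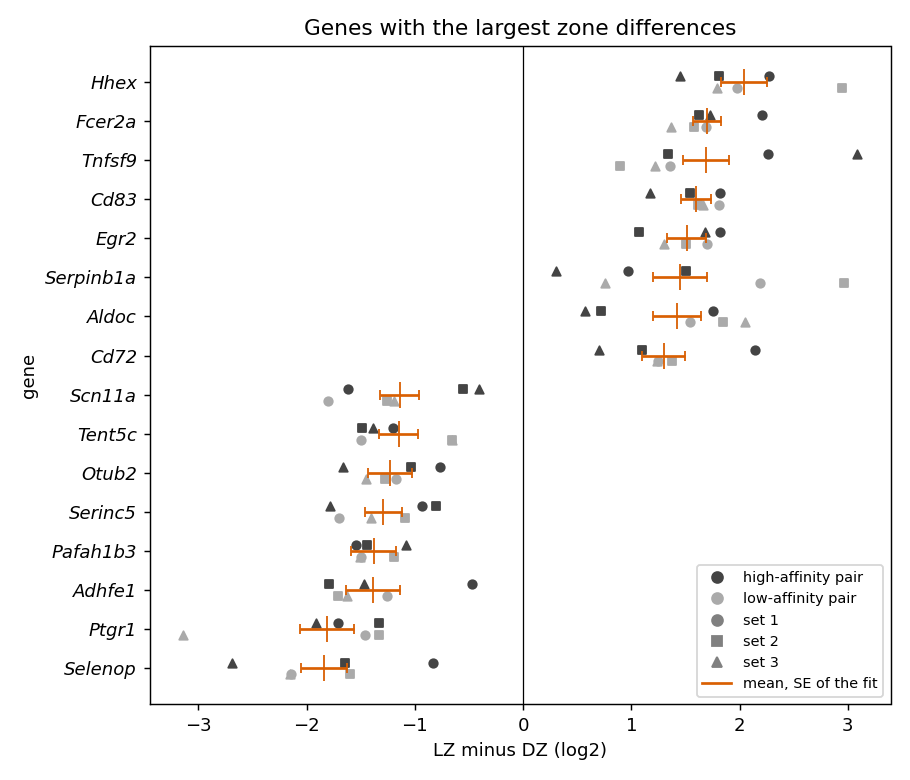
LZ minus DZ difference (log2) of the 8 genes with the largest rise and the 8 with the largest fall. Points are the 6 pairs of arrays of the same matched set and affinity, and the orange marks are the mean with the SE of the fit. All pairs of a gene lie on the same side of 0, which the naming rule required. The means run from -1.84 for Selenop to 2.04 for Hhex.

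Light zone markers fixed in advance were higher in LZ cells, with a median difference of 0.71 over 19 tested members (camera adjusted p = 1.34e-25, 0.0158 with an estimated correlation). Of these, 7 rose, 0 fell and 12 did not pass; 12 rose when adjusted over the list alone. Cd83, Fcer2a, Egr2 and the sort gene Cd86 are among the 7. NF-kB targets, a readout of CD40 and antigen receptor signalling, had a median of 0.50 over 15 members (adjusted p = 1.17e-15, 0.0293 with an estimated correlation). Of these 15, 8 are also light zone markers, Cd83 and Nfkbia among them, so the 2 lists are not separate results. Cd83 and the NF-kB inhibitor gene Nfkbia (0.95 ± 0.16, adjusted p = 0.0278, lost in 10 of 12 fits without 1 array) rose, and 10 members rose when adjusted over the list alone. Genes of cholesterol biosynthesis had a median of 0.49 (adjusted p = 2.35e-15, 0.0395 with an estimated correlation). None of the 14 tested members passed over all genes by limma without the block and 1 did with it, Msmo1 (0.60 ± 0.13, adjusted p = 0.08, 0.0376 with the replicate block); 11 rose when adjusted over the list alone, among them Hmgcs1 (0.61, adjusted p = 0.158, 0.0282 with array weights). In the opposite direction, genes of the G2 and M phases had a median of -0.40 over 24 members (adjusted p = 8.06e-16, 0.0395 with an estimated correlation). The mitotic kinesin gene Kif20a (-0.74), the cyclin gene Ccnb2 (-0.87), Cdc20 (-0.92) and Cdca8 (-0.67) fell, and 11 members fell when adjusted over the list alone. The calls of Ccnb2, Cdc20, Cdca8 and Kif20a were lost without matched set 3, and in 9, 8, 12 and 6 of the 12 fits without 1 array. Dark zone markers had a median of -0.38 over 13 members (adjusted p = 1.89e-08, 0.0417 with an estimated correlation). Of these, 3 fell: Pafah1b3, the translesion polymerase gene Polh (-0.93 ± 0.14, lost in 5 of 12 fits without 1 array) and the forkhead factor gene Foxp1 (-0.58 ± 0.11, lost in each of the 12 fits without 1 array); 5 fell when adjusted over the list alone. With the replicate block and an estimated correlation together, light zone markers passed (adjusted p = 0.0361) and the other 4 of these lists did not (0.0538 to 0.0715).

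The calls of 8 other lists in LZ minus DZ were lost with an estimated correlation. Higher medians were found for immediate early genes (0.36, adjusted p = 4.68e-07; 0.134 with an estimated correlation), MHC class II presentation (0.34, 2.9e-06; 0.195), memory B cell genes (0.23, 0.0324; 0.0969) and Myc targets (0.10, 0.0324; 0.393). Lower medians were found for oxidative phosphorylation (-0.17, adjusted p = 8.51e-05; 0.225 with an estimated correlation), plasma cell differentiation (-0.26, 0.000199; 0.0579) and the interferon response (-0.19, 0.0158; 0.0765). Egr2 in the immediate early list, Hhex in the memory list and Jchain, the joining chain of secreted immunoglobulin (-0.97, adjusted p = 0.0427, lost in 10 of 12 fits without 1 array), were the called members of these lists. Markers of macrophages, a cell type the sort should remove, also had a higher median in LZ cells (0.17, adjusted p = 0.0324; 0.109 with an estimated correlation and 0.0562 with the replicate block), and none of their 5 members passed without or with the block. Cd68 (0.65) passed with array weights (adjusted p = 0.00774), without LZ_high replicate 3 (0.0173), without matched set 3 (0.0371, 0.0337 with the block) and with the block without the LZ_high array of set 3 (0.00831). The memory list passed at 0.0324 without the block and not with it (0.0673). At the preset correlation the memory call was also lost without DZ_high replicate 2, DZ_low replicate 3, LZ_high replicate 2 or LZ_low replicate 2 or 3 (adjusted p = 0.0758 to 0.147), and that of the interferon response without LZ_high replicate 3 (0.0635). The macrophage call was lost without DZ_high replicate 2 or 3, DZ_low replicate 1, LZ_high replicate 2 or LZ_low replicate 2 or 3 (0.0715 to 0.147), and that of Myc targets without DZ_high replicate 3, DZ_low replicate 2, LZ_high replicate 1 or 3 or LZ_low replicate 3 (0.0502 to 0.276). The macrophage median was 0.45 without DZ_high replicate 3, 0.37 without DZ_low replicate 3, 0.49 without LZ_high replicate 1 and 0.43 without LZ_low replicate 1. It was 0.083 without DZ_low replicate 1, 0.082 without LZ_high replicate 2, 0.10 without LZ_high replicate 3 and 0.09 without LZ_low replicate 3. The median of Myc targets was 0.05 without DZ_low replicate 2, and that of oxidative phosphorylation -0.10 without DZ_low replicate 3. With no filter the medians of the interferon response (-0.01, adjusted p = 0.297) and of macrophages (0.02, 0.441) were not called, and with array weights that of Myc targets was not (0.06, 0.119). Without matched set 3 the calls of memory genes (0.15, 0.238), the interferon response (-0.07, 0.141) and macrophages (0.11, 0.0594) were lost, and also with the block (0.288, 0.118 and 0.0636). With the block without the LZ_high array of set 3, those of memory genes (0.26, 0.0658) and the interferon response (-0.13, 0.114) were lost. Lists not called were G1/S and DNA replication (median 0.02), the unfolded protein response (-0.06), B cell and GC identity (0.11), somatic hypermutation and repair (0.05), apoptosis regulators (0.07), glycolysis (-0.04), dissociation stress (0.06), T cell markers (0.04), granulocyte markers (-0.04) and follicular dendritic and stromal cell markers (-0.04). Among B cell regulators, Irf4 (0.74), Myc (0.71), Bcl6 (0.18), Bach2 (-0.38), Xbp1 (-0.34), Foxo1 (-0.23), Ptprc (0.37), Mki67 (-0.42) and Pax5 (-0.07, but 0.10 without LZ_low replicate 3) did not pass without or with the block. Myc passed with the block without the LZ_high array of set 3 (0.98, adjusted p = 0.04), and Ccr6 (0.50, adjusted p = 0.174) passed with the replicate block (0.0463) and with array weights (0.038).

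**Figure D3:**
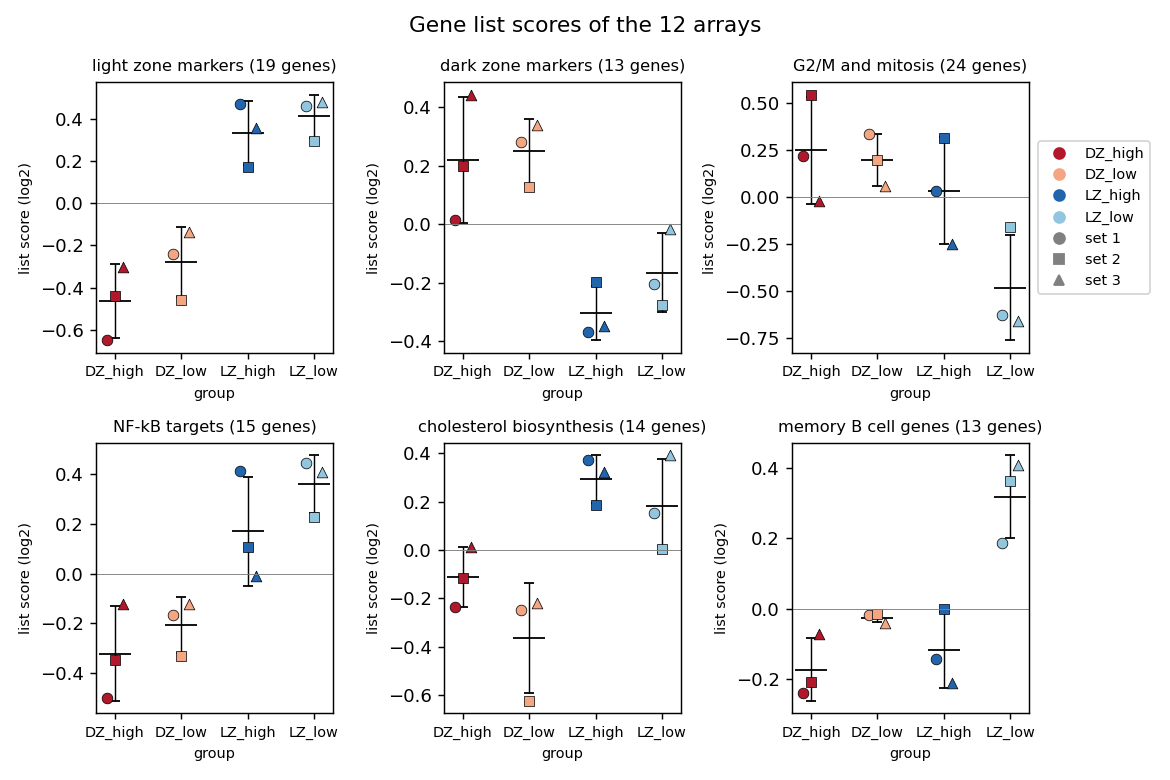
Scores of 6 gene lists in each array (mean of the members' log2 values, each centred on its mean over the 12 arrays), by group. Points are arrays, lines group means and bars the SD (n = 3); light zone markers average -0.46 in DZ_high, -0.28 in DZ_low, 0.33 in LZ_high and 0.41 in LZ_low, and memory B cell genes reach 0.32 in LZ_low against -0.12 in LZ_high.

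The zone difference was also taken at each affinity. At high affinity 4 genes passed, all higher in LZ cells: Fcer2a (1.85 ± 0.18), Cd83 (1.51 ± 0.19), the sort gene Cd86 (1.47 ± 0.15) and Tnfsf9 (2.23 ± 0.29). At low affinity Hhex (2.24 ± 0.29), Cd83 (1.70 ± 0.19) and Fcer2a (1.54 ± 0.18) were higher and Myl4, a myosin light chain gene, was lower (-1.16 ± 0.15); Myl4 lies outside the naming rule and was chosen after its value was seen. Each moved the same way in 3 of 3 sets. Cd83 and Fcer2a passed at both affinities. The interaction of zone and affinity had 0 genes past the threshold, so no gene was shown to differ between the affinities in its zone difference. With the replicate block 9 genes passed at high and 25 at low affinity, 5 of them at both. All 47 genes called in the mean had the same sign at both affinities, which their choice by that mean largely fixes. Over all tested genes 56% had the same sign. Of the 47, 6 had an unadjusted interaction p under 0.05 by limma, against 177 of all 11206. Across all tested genes, which are not independent replicates, the differences at the 2 affinities had a Pearson correlation of 0.316 and a Spearman correlation of 0.219. The high-affinity count was 2 without DZ_high replicate 2, DZ_low replicate 2 or 3, LZ_high replicate 1 or LZ_low replicate 3; the low-affinity count was 0 without DZ_low replicate 1 or 2 or any LZ_low replicate, and 2 without DZ_high replicate 2. Both counts were 0 when only the groups compared were fitted.

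The second comparison asks what distinguishes cells of high from cells of low affinity. In the LZ, memory B cell genes were lower in high-affinity cells, with a median of -0.37 over 13 members (camera adjusted p = 3.05e-06, 0.0154 with an estimated correlation, 0.0486 with that and the replicate block). The median was -0.28, -0.28 and -0.53 in sets 1, 2 and 3, and 11 of 13 members had lower values. It was -0.29 without matched set 3 and -0.32 without LZ_low replicate 3, with the call kept in both (adjusted p = 7.87e-06 and 7.34e-06). Markers of cells the sort should remove also had lower medians and were not called: macrophages (-0.14, 4 of 5 members lower, adjusted p = 0.302), granulocytes (-0.34, 7 of 8 lower, 0.512) and T cells (-0.15, 4 of 5 lower, 0.16). In set 3 these were -1.03, -1.04 and -0.04, and the LZ_low array of that set had the highest macrophage and T cell scores of the 12 arrays (0.72 and 0.27). No memory gene passed over all genes. Ccr6, a chemokine receptor gene (-0.74 ± 0.18), and Hhex (-1.15 ± 0.29) passed when adjusted over the list alone (adjusted p = 0.0154 for each). Genes of the G2 and M phases had a median of 0.51, and all 24 members had higher values at high affinity (adjusted p = 5.07e-14, 0.0948 with an estimated correlation). The set medians were 0.56, 0.42 and 0.39; Bub1b (0.65), Ccna2 (0.59), Cdc20 (0.78) and Kif20a (0.55) are among the 5 members that passed over the list alone. Myc targets and ribosome biogenesis had a median of 0.29, with 23 of 24 members higher (adjusted p = 6.62e-08, 0.0948 with an estimated correlation), and G1/S genes 0.24 (5.05e-06, 0.225 with an estimated correlation). Oxidative phosphorylation was higher (0.17, adjusted p = 0.00049), and MHC class II presentation (-0.27, 0.00942), apoptosis regulators (-0.27, 0.00942), B cell and GC identity (-0.16, 0.0144) and the interferon response (-0.31, 0.0185) were lower. With an estimated correlation their adjusted p was 0.408, 0.564, 0.225, 0.0948 and 0.11, in that order. At the preset correlation the apoptosis call was lost without LZ_high replicate 3 (median -0.10, adjusted p = 0.203) and that of B cell identity without LZ_high replicate 2 (0.0634). The apoptosis call was also lost with the stricter filter (-0.29, 0.0641), without matched set 3 (-0.10, 0.142, or 0.15 with the block) and with the block without the LZ_high array of that set (-0.08, 0.209), where that of the interferon response was lost too (-0.26, 0.0512). That of MHC class II was lost without LZ_high replicate 1 or 2 or LZ_low replicate 3 (medians -0.17, -0.14 and -0.11; adjusted p = 0.135, 0.12 and 0.209), and that of the interferon response without LZ_high replicate 1 or 3 or LZ_low replicate 2 (0.0821, 0.0572 and 0.0597). Other medians that moved by more than 1.5 times kept their calls: memory genes without LZ_low replicate 1 (-0.56), G1/S genes without LZ_low replicate 2 or 3 (0.13 and 0.38), oxidative phosphorylation without LZ_low replicate 2 (0.11) and B cell identity without LZ_high replicate 3 (-0.26).

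No single gene passed in this contrast by limma: 466 of 11206 genes had an unadjusted p under 0.05, 560 being expected by chance, and 0 passed with the replicate block (891 unadjusted). The genes with the smallest p were Eef1e1 (0.83 ± 0.17), a factor of the tRNA synthetase complex, Cmss1 (1.04 ± 0.21) and Tnfsf9 (1.20 ± 0.29) at higher values in high-affinity cells. The adhesion receptor gene Cd2 (-1.11 ± 0.19), Arhgef3 (-1.23 ± 0.22) and the protease inhibitor gene Serpinb1a (-1.79 ± 0.35) had lower values. Each had the same sign in 3 of 3 sets, and the smallest adjusted p was 0.784. Differences of the sort genes and regulators were -0.30 for Cxcr4, -0.14 for Cd86, -0.02 for Ptprc, -0.18 for Bcl6, -0.86 for Bach2, 0.56 for Irf4, 0.02 for Xbp1, 0.22 for Myc, -0.14 for Foxo1, -0.08 for Pax5 and 0.58 for Mki67. Those of Xbp1, Pax5 and Ptprc changed sign when LZ_high replicate 3 was left out (-0.30, 0.21 and 0.13).

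In the DZ, 10 lists passed at the preset correlation (6 without DZ_high replicate 2), and none passed with an estimated one. G1/S and DNA replication had a median of 0.36 with 23 of 24 members higher in high-affinity cells (camera adjusted p = 1e-10, 0.173 with an estimated correlation), with Gins2 at 0.66 and Rrm1 at 0.47. The unfolded protein response had a median of 0.25 (adjusted p = 0.000293, 0.363 with an estimated correlation), and its member Pdia4, an ER protein disulfide isomerase gene (1.29 ± 0.31), passed over the list alone. Plasma cell genes had a median of 0.23 (0.00138, 0.173 with an estimated correlation), with Fkbp11 at 0.69 and Jchain at 0.51. Cholesterol biosynthesis (0.27, adjusted p = 0.000309), oxidative phosphorylation (0.14, 0.00138), glycolysis (0.19, 0.00887) and Myc targets (0.14, 0.0401) were higher; with an estimated correlation the adjusted p was 0.363, 0.403, 0.403 and 0.456. Light zone markers were lower in high-affinity DZ cells (median -0.11, adjusted p = 0.00722, 0.403 with an estimated correlation), and Fcer2a (-1.11 ± 0.18), the sort gene Cd86 (-0.81 ± 0.15), Cd69 (-1.19 ± 0.32) and Slamf1 (-0.69 ± 0.22) passed over the list alone. B cell and GC identity was lower (-0.15, adjusted p = 0.0169, 0.173 with an estimated correlation). Granulocyte markers, of a cell type the sort should remove, were higher in the same samples (0.43, adjusted p = 0.005, 0.403 with an estimated correlation). The calls of G1/S, the unfolded protein response and plasma cell genes were kept at the preset correlation in each fit without 1 array; those of the other lists were not. Without DZ_low replicate 2 the calls of cholesterol biosynthesis, oxidative phosphorylation, glycolysis and Myc targets were lost (adjusted p = 0.1, 0.185, 0.178 and 0.565); without DZ_high replicate 2 those of light zone markers, Myc targets, B cell identity and granulocytes (0.0581, 0.211, 0.188 and 0.27); without DZ_low replicate 1 those of Myc targets, B cell identity, glycolysis and granulocytes (0.0643 to 0.0875). Without DZ_low replicate 3 those of light zone markers, B cell identity and granulocytes were lost (0.0566 to 0.108), without DZ_high replicate 1 those of light zone markers (median 0.002, adjusted p = 0.118) and Myc targets (0.1), and without DZ_high replicate 3 that of glycolysis (0.0954). The call of Myc targets was also lost with no filter (0.118) and after median centring (0.0582), that of light zone markers with the block without the LZ_high array of set 3 (0.0538), and that of granulocytes without matched set 3 (0.31, 0.0804). G2/M genes (0.07, adjusted p = 0.051; -0.09, 0.35 and -0.06 in sets 1, 2 and 3) and memory B cell genes (-0.11, 0.172, 8 of 13 members lower; -0.19, -0.04 and 0.004) were not called in the DZ. Several medians moved by more than 1.5 times without 1 array. Without DZ_low replicate 2 the medians were 0.11 for cholesterol biosynthesis, 0.025 for oxidative phosphorylation, 0.09 for glycolysis, 0.02 for Myc targets, 0.12 for plasma cell genes, 0.10 for the unfolded protein response, -0.22 for light zone markers, -0.27 for B cell identity and 0.855 for granulocytes. Without DZ_low replicate 1 they were 0.45 for plasma cell genes, 0.375 for the unfolded protein response, 0.08 for Myc targets, 0.11 for glycolysis and 0.28 for granulocytes. Without DZ_low replicate 3 they were 0.005 for light zone markers, 0.23 for Myc targets and 0.32 for glycolysis. Without DZ_high replicate 2 they were -0.03 for light zone markers, 0.06 for Myc targets and 0.15 for granulocytes. Without DZ_high replicate 3 they were 0.085 for glycolysis and 0.06 for oxidative phosphorylation, and without DZ_high replicate 1 that of granulocytes was 1.04.

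No single gene passed in the DZ by limma either: 247 of 11206 had an unadjusted p under 0.05 (597 with the replicate block, where 0 passed). The genes with the smallest p were Vat1 (0.75 ± 0.17), Tmem267 (1.34 ± 0.31) and the cytokine receptor subunit gene Il6st (0.95 ± 0.22) at higher values, and Fcer2a, Cd86 and Pdzd2 (-0.70 ± 0.14) at lower values. Each had the same sign in 3 of 3 sets, and the smallest adjusted p was 0.734, for Fcer2a. Without DZ_low replicate 1 the count was 1, Pdia4 (1.75, adjusted p = 0.0102). Differences of the other regulators were 0.04 for Cxcr4, -0.37 for Ptprc, -0.47 for Bcl6, -0.59 for Bach2, 0.61 for Irf4, 0.42 for Xbp1, 0.35 for Myc, -0.25 for Foxo1, -0.37 for Pax5, -0.11 for Ccr6 and 0.07 for Mki67. Those of Cxcr4, Ccr6 and Mki67 changed sign when DZ_high replicate 3 (-0.23), DZ_low replicate 2 (0.03) and DZ_high replicate 2 (-0.13) was left out.

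**Figure D4:**
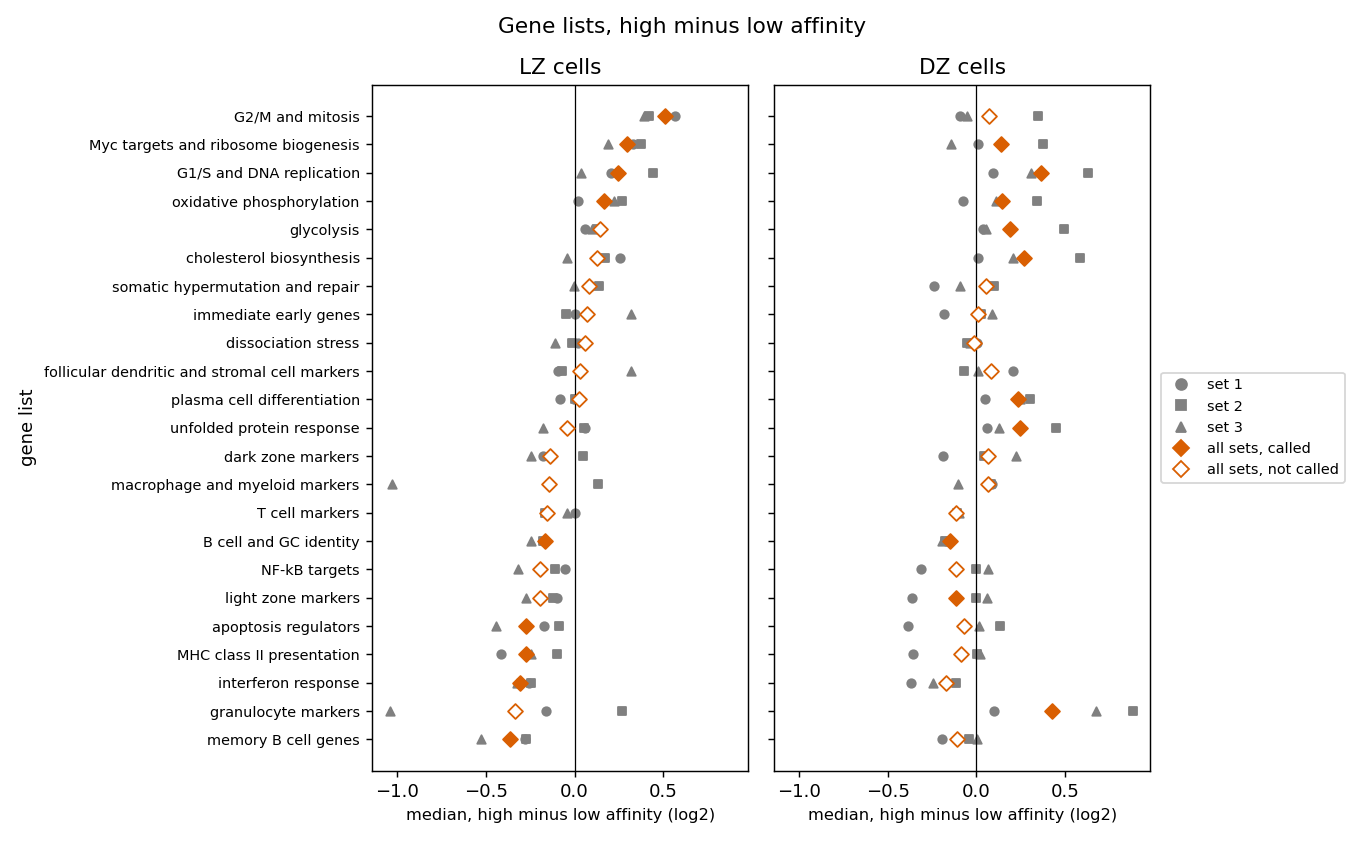
Median high minus low affinity difference (log2) of the members of 23 gene lists, in LZ and in DZ cells. Grey points are the medians in the 3 matched sets, and filled diamonds mark lists called at the preset correlation, 9 in LZ and 10 in DZ; with an estimated correlation only memory B cell genes in LZ (-0.37) passed.

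Averaged over both zones, memory B cell genes were lower in high-affinity cells (median -0.30, camera adjusted p = 5.67e-05, 0.0389 with an estimated correlation). With the replicate block and an estimated correlation together their adjusted p was 0.102. Without DZ_low replicate 3 the median was -0.20. The averaged value rests more on the LZ (-0.37) than on the DZ (-0.11), and so does that of G2/M genes (0.51 and 0.07). At the preset correlation 15 lists passed, 8 higher and 7 lower, and memory genes alone passed with an estimated one; by fry 2 lists passed without the block and 7 with it. The others with the largest medians were G1/S genes (0.34, 7.56e-12; 0.0744 with an estimated correlation), the interferon response (-0.35, 0.00474; 0.0744), G2/M genes (0.29, 4.76e-10; 0.084) and Myc targets (0.20, 9.59e-07; 0.084). No gene passed by limma (588 unadjusted, against 1059 and 0 past the threshold with the replicate block). Fcer2a had the smallest p, with -0.95 ± 0.13 and lower values in 6 of 6 pairs (adjusted p = 0.123, 0.0661 with the replicate block). It was followed by Cd2 (-0.83), Arhgef3 (-0.85), Cmss1 (0.84), Eef1e1 (0.63) and Syce2 (0.46), each with the same sign in 6 of 6 pairs. Across genes the affinity differences in the 2 zones had a Pearson correlation of 0.227 and a Spearman correlation of 0.233.

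The interaction asks whether the affinity difference itself differs between the zones. It had 0 genes past the threshold by limma (177 of 11206 unadjusted; 0 and 408 with the replicate block). The genes with the smallest p and a more positive affinity difference in LZ than in DZ were Cd69 (1.76 ± 0.45, positive in 2 of 3 sets), Cdkal1 (0.76 ± 0.21) and Antxr2 (1.20 ± 0.36). Those with a more negative one in LZ were Tmem43 (-0.97 ± 0.26), Il6st (-1.14 ± 0.32) and Coro2b (-1.24 ± 0.35). The adjusted p was 1 for each. At the preset correlation 6 lists passed (2 without DZ_low replicate 3, 3 without LZ_low replicate 2), and none with an estimated correlation; G2/M genes had the lowest adjusted p, with a median of 0.43 (5.25e-07, 0.484 with an estimated correlation), or 0.281 without LZ_high replicate 2 and 0.285 without DZ_high replicate 3. Granulocyte markers were among the 6, with a median of -0.98 (0.0107, 0.583 with an estimated correlation). That median was -0.11 without matched set 3 (adjusted p = 0.394), -0.14 with array weights (0.286), -0.47 without DZ_high replicate 2 (0.173), -0.51 without LZ_high replicate 1 (0.251), -0.59 without DZ_high replicate 3, -0.64 without LZ_low replicate 3 and -1.47 without LZ_high replicate 2.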

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

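Of the tests below, those on DZ cells in the LZ sort and on granulocyte RNA were chosen only after the result was seen. The 6 lists below were picked out because a test of the difference itself, the interaction of zone and affinity, passed at camera's preset correlation. Each call was lost with an estimated correlation and with fry. Of 100 splits of the arrays, 25 gave as many lists, so chance cannot be excluded for these differences. Single outlying samples were not tested for in groups of 3 arrays; the values without 1 array are given instead.

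The high minus low affinity difference of G2/M genes was larger in LZ than in DZ cells, by a median of 0.43 (adjusted p = 5.25e-07, 0.484 with an estimated correlation), or 0.281 without LZ_high replicate 2 and 0.285 without DZ_high replicate 3. In LZ cells these genes had a median of 0.51. DZ cells within the high-affinity LZ sort would lower LZ genes and raise DZ genes along with it. Over 42 called zone genes the slope of the affinity difference on the zone difference was -0.21 (SE 0.06). The G2/M median would need -1.27, which argues against cells of the average DZ profile as the whole cause. The slope is negative, the direction that such cells predict, so they are not excluded as a part of the cause. DZ cells richer in G2/M genes than that average would need a weaker slope, and they were not tested. The SE of the slope is taken across genes, which are not independent replicates, and does not measure the spread between arrays. The same arrays gave the zone calls. The LZ_high array of set 3 does not raise the LZ difference: it had the lowest G2/M score of its group (-0.25, against 0.036 and 0.318). Without it the LZ median was 0.574 (camera adjusted p = 3.76e-17), which says nothing about the other arrays. The scaling of the arrays is argued against by a median of at least 0.485 under another quantile normalization or median centring. A difference that goes with affinity itself was not tested and stays open.

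The granulocyte list had an interaction of -0.976 (adjusted p = 0.0107, 0.583 with an estimated correlation), with higher values at high affinity in DZ cells (median 0.428). The interaction was -0.106 without matched set 3 (adjusted p = 0.394), -0.14 with array weights (0.286), and without 1 array from -0.47 (DZ_high replicate 2) and -0.507 (LZ_high replicate 1) to -1.467 (LZ_high replicate 2), with -0.591 without DZ_high replicate 3 and -0.644 without LZ_low replicate 3. The levels of some members differed widely between arrays: S100a9 ran from 6.07 to 10.37 and Ngp from 4.71 to 8.72, while Elane stayed between 5.3 and 5.74. Whether granulocyte RNA in some of the arrays is the source of the list's affinity differences stays open. With group means removed the members' values had a mean pairwise correlation of 0.59 over the 12 arrays, but the list's scores lay from -0.896 to -0.576 in set 1 and from 0.326 to 1.031 in set 2. A difference between the sets that is alike in all groups cancels in the affinity contrasts, so the 0.59 is no support for granulocyte RNA as their source; with set means removed as well the correlation was 0.28, between the 0.1 and 0.4 set as bounds. The sort for donor IgG1+ cells should remove granulocytes, and 0 of the 8 tested members are in another list. A difference carried by 1 array cannot be told apart from one between the groups, since the median was 0.15 without DZ_high replicate 2 and between 0.28 and 1.04 without any other DZ array, the lowest being between the 0.1 and 0.2 set as bounds; it was 0.834 with array weights (adjusted p = 0.00141). A difference that goes with affinity itself was not tested and stays open.

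Myc targets and ribosome biogenesis had an interaction of 0.218 (adjusted p = 0.0069, 0.583 with an estimated correlation). Memory B cell genes had one of -0.395 (0.0069, 0.158 with an estimated correlation), the unfolded protein response one of -0.215 (0.00691, 0.583 with an estimated correlation) and plasma cell differentiation one of -0.227 (0.0368, 0.583 with an estimated correlation). Leaving out 1 array left between 2 (without DZ_low replicate 3) and 7 (without DZ_high replicate 3) lists past the threshold in the interaction; it left 3 without LZ_low replicate 2. The call of G2/M genes was kept in each of the 12 fits without 1 array at the preset correlation. That of memory genes was lost without LZ_low replicate 2 (-0.326, adjusted p = 0.0573) and that of Myc targets without DZ_low replicate 3 or LZ_low replicate 2 (0.091 and 0.151, adjusted p = 0.132 and 0.0657). Memory genes had -0.254 without LZ_low replicate 3, and Myc targets 0.107 without LZ_high replicate 1 and 0.139 without DZ_high replicate 3. That of the unfolded protein response was lost without DZ_high replicate 1, DZ_low replicate 2 or 3, LZ_high replicate 3 or LZ_low replicate 1 (0.0523 to 0.154); its median was -0.072 without DZ_low replicate 2 and -0.136 without DZ_high replicate 1. That of plasma cell genes was lost without DZ_high replicate 1 or 2, DZ_low replicate 2 or 3, LZ_high replicate 1 or 2 or LZ_low replicate 1 (0.0808 to 0.207), with medians of -0.106 without LZ_low replicate 1, -0.151 without LZ_high replicate 2 and -0.379 without DZ_low replicate 1, where the call was kept; it was also lost with the stricter filter (-0.259, 0.128). That of granulocytes was lost without DZ_high replicate 2, DZ_low replicate 1 or 3, LZ_high replicate 1 or 3 or LZ_low replicate 2 or 3 (0.0614 to 0.251). Without matched set 3 the memory and granulocyte calls were lost (medians -0.116 and -0.106, adjusted p = 0.132 and 0.394).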

How the results depend on the processing

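The fits without matched set 3, the blocked fits without that set or its LZ_high array, and the block with an estimated correlation or with fry were chosen after seeing the data; the other alternatives were planned. Of 25 gene values past the threshold, 9 kept it under every setting that gave a value (Cd83, Cd86, Egr2, Fcer2a, Hhex, Ptgr1, Selenop, Serinc5 and Tnfsf9) and 16 lost it in at least 1; of the others, 20 passed in at least 1. Of 53 called list shifts, 46 were lost with an estimated correlation, 41 with fry and 3 with the replicate block, and 0 turned in the test's direction. With an estimated correlation the values, the fit and the contrast stayed the same. Those 46 losses therefore follow from how camera treats the correlation between members. The cause of the other changes was not tested. The signal limits what could be tested: 8732 genes lay below the array median in all but at most 2 of the 12 arrays.

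For LZ minus DZ, 47 genes became 135 with the replicate block, 110 with a random block, 80 after quantile normalization, 28 after median centring, 212 with array weights, 87 without matched set 3, 167 with the block without the LZ_high array of set 3, and 95 with the block without set 3. Without 1 array, the count was 12 without DZ_low replicate 1, 13 and 15 without LZ_low replicates 2 and 1, 16 and 18 without LZ_high replicates 1 and 2, 20 without DZ_low replicate 2, 22 and 27 without DZ_high replicates 1 and 2, 28 without DZ_low or LZ_low replicate 3, 33 without DZ_high replicate 3 and 67 without LZ_high replicate 3. At high affinity 4 became 9 with the block, 12 with a random block, 22 with array weights, 13 with all probe sets and 0 with only the groups compared (2 to 5 without 1 array). At low affinity 4 became 25 with the block, 18 with a random block, 7 after quantile normalization, 29 with array weights, 40 with the block without the LZ_high array of set 3, and 0 with only the groups compared (0 to 5 without 1 array). For affinity averaged over the zones, 0 became 1 with a random block, quantile normalization or array weights (Fcer2a each time) and 2 with all probe sets. In the DZ, 0 became 5 with all probe sets and 1 without DZ_low replicate 1 (0 to 1 without 1 array).

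Called lists numbered 13 for LZ minus DZ and 5 with an estimated correlation, or 1 with that and the block, and 9 by fry without or with the block (10 to 13 without 1 array). They numbered 9 for affinity in LZ and 1 with an estimated correlation, with fry or with the block and an estimated correlation, and 2 by fry with the block (9 to 11 without 1 array). In the DZ they numbered 10, and 0 with each of these 3 settings and by fry with the block (6 without DZ_high replicate 2, to 13 without DZ_high replicate 3). Averaged over the zones they numbered 15, 1 with an estimated correlation, 2 with fry, 7 by fry with the block (G1/S, G2/M, Myc targets, B cell identity, memory, glycolysis and interferon lists) and 0 with the block and an estimated correlation (10 without DZ_high replicate 1, to 15). In the interaction they numbered 6, 0 with each of the 3 settings and by fry with the block, and 3 with the stricter filter (2 to 7 without 1 array). With the replicate block at the preset correlation, camera called 11 lists for LZ minus DZ, 10 for affinity in LZ and 10 in the DZ. It called 14 averaged over the zones and 6 in the interaction.

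Of 248 gene values, 11 changed sign in at least 1 setting, 0 of them past the threshold. For Xbp1 in LZ (affinity, 0.02) the values were -0.001 after median centring, -0.22 with array weights, -0.11 without set 3 with or without the block, -0.18 with the block without the LZ_high array of set 3, and -0.30 to 0.28 without 1 array; averaged over the zones, 0.22 became -0.045 with array weights. For Pax5 in LZ minus DZ (-0.07) they were 0.085 with array weights, 0.13 without set 3 with or without the block, and -0.17 to 0.10 without 1 array. For Cxcr4 in the DZ (0.04) they were -0.19 with array weights, -0.20 without set 3 with or without the block, and -0.23 to 0.20 without 1 array. Xaf1 in LZ minus DZ (-0.26) was 0.07 without set 3 with or without the block. With the block without the LZ_high array of set 3, Pax5 in LZ (-0.08) was 0.02 and Cflar in LZ (-1.09) was 0.067. Without 1 array, values ran from -0.33 to 0.62 for Lyz2 in LZ minus DZ (0.17), -0.13 to 0.20 for Mki67 in the DZ, -0.27 to 0.029 for Ccr6 in the DZ, -0.22 to 0.13 for Ptprc in LZ, -0.42 to 0.21 for Pax5 in LZ, and -1.75 to 0.071 for Cflar in LZ.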

Other observations

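Of the tests below, those of a batch difference and of signal spread in set 3 were chosen only after the result was seen. Each set was compared with the mean of the other sets in the same group. Set 3 lay on the same side of that mean in all 4 groups of cells for 12 of the 24 gene lists, 10 higher and 2 lower. No test was made. In some groups set 3 still lay between the others: the G1/S score in DZ_low was -0.114 in set 3, -0.09 in set 1 and -0.405 in set 2. The light zone marker score in LZ_high was 0.356, 0.469 and 0.17, in that order. With independent signs 3 of 24 would be expected, and the lists are not independent; set 1 did so for 8 and set 2 for 9. Among the 12 were the following. MHC class II genes were higher in set 3 by 0.46 (mean of the 4 groups), immediate early genes by 0.44, glycolysis genes by 0.39 (SD 0.04 over the 4 groups), G1/S genes by 0.17 and dissociation stress genes by 0.18, each in 4 of 4 groups. G2/M genes had a difference of -0.33, lower in 4 of 4 groups. Granulocyte markers did not follow this split (0.09, SD 0.71, higher in 2 of 4 groups).

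Of the variance of the first component 84.4% lay between the sets, which restates the position of set 3 and does not say what the sets differ in; a batch cannot be told apart from any other difference between the sets. The spread of signal is argued against as the cause of that position, since 0 of the 4 arrays had an interquartile range outside that of the other 8 (2.63 to 2.94, within 2.54 to 3.02). Stress during cell handling cannot be told apart from the set, since the stress score of set 3 was 0.12 against -0.06, a difference of 0.18, and the score moved with the set in every group. No biological explanation was tested, since the design gives none for the sets.

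When all probe sets were tested, 5 passed for high minus low affinity in the DZ, all higher at high affinity by 1.95 to 2.75 on the log2 scale. All 5 match the same 5 gene symbols, and 1 matches a sixth, so they form 1 family of cross-matching probe sets, count as 1 result and are not named as a gene; 2 of them also passed in the mean of both zones.

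Other splits of the same arrays were fitted as the real one was. For LZ minus DZ, 1 of 100 splits, the real one, gave as many genes (47, the highest other 3), so chance can be excluded at that share. With the block it gave 135 against 0 for every other of the 32 splits that part all pairs. For its lists, 2 of 100 gave as many (13, the highest other 13), and splits that part every pair gave at most 12. That share is under 0.05, but it concerns the count alone and does not say which lists differ. At high and at low affinity the 10 splits of 6 arrays are too few for a share under 0.05: the real split called 4 genes at each and the highest other 0, and 1 of 10 splits gave as many. The same holds for affinity within a zone, where the real and all other splits called 0 genes in LZ and in DZ (10 of 10 as large, which a count of 0 makes certain), and the lists numbered 9 in LZ and 10 in DZ against a highest other of 5 in each (1 of 10 as large). For affinity averaged over the zones, 1 of 100 splits, the real one, gave as many lists (15, the highest other 12, also 12 among splits parting every pair). Here too the share concerns the count alone and does not say which lists differ. For the genes of that contrast and of the interaction the count was 0, so 100 of 100 splits were as large in each by necessity and the splits say nothing about them. Chance cannot be excluded for the lists of the interaction (25 of 100; 6, the highest other 12, and 15 among the 32 splits parting every pair, of which 9 gave as many). In each of these 2 contrasts a split that parts 2 of the 6 pairs called 29 genes. It puts all arrays of set 2 on 1 side and all of set 3 on the other, which may point to a structure of the samples. That layout was read off after the count was seen. For LZ minus DZ, the 2 drawn splits with that layout called 0 genes. Of the 3 drawn splits of that kind in each of the other 2 contrasts, 1 called 0 genes for the affinity mean and 2 did in the interaction. In those contrasts 38 of all 40 and 33 of all 35 splits parting 2 pairs called 0. Splits that part every pair called 0 without the block and at most 1 with it.

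For 13 combinations of list and contrast, the median, the mean and the direction of the test differed in sign, and 0 of these were called. They were somatic hypermutation in LZ minus DZ; plasma cell genes, the unfolded protein response and dissociation stress for affinity in LZ; dark zone markers, immediate early genes, somatic hypermutation and T cell markers for affinity in DZ; somatic hypermutation and dissociation stress for affinity averaged over the zones; and light zone markers, glycolysis and dissociation stress in the interaction.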
